A study of Mus musculus with 6 samples.

How the data were processed

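RNA of 6 libraries was analysed, 2 from PBS-treated and 4 from IL-10/Fc-treated mice, each made from 500 sorted tumour-infiltrating T cells with the Smart-Seq2 protocol. Smart-Seq2 primes on the poly(A) tail, copies whole transcripts, carries no molecular identifiers and does not mark strand. Reads of a gene and of an antisense or overlapping partner can therefore not be told apart, and PCR copies count as separate reads. The sort purity was above 99%, per the labels' protocols. The labels name replicates and do not state that each library came from its own mouse, so p-values measure the spread between these samples, which may in part be technical.

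The authors deposited 1 table of whole-number counts per gene for each library, and 1 table for the whole series with the same counts and their own comparison. Tools named per the submitters' processing notes are Trimmomatic, Bowtie2 2.2.9, TopHat2 2.1.1, Cufflinks 2.2.1, Cuffdiff and DESeq2, with the mouse build GRCm38 (mm10). The tool that counted reads per gene is not given in the sources used here. In the series table the authors deposited log2 fold changes with standard errors, a p-value and an adjusted p-value per gene, and a mean of normalized counts, a signal that is never negative. The Wald statistic in the deposited table, a score, is the log2 fold change divided by its standard error, per the file headers and values. The 15898 listed genes are those with an adjusted p-value in that table, the smallest deposited mean is 6.77, and the adjusted p-values equal a Benjamini-Hochberg adjustment over the listed genes to within 3.54e-06. Genes outside this list were not analysed here, so the totals per library cover the listed genes. File columns number the PBS libraries 2 and 3 where the titles number them 1 and 2, and the titles were followed. Coordinates are those of the deposited files on GRCm38, 1-based.

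Depth was 26738871 to 36941814 counts per library, at which 3 counts equal 0.0812 to 0.112 CPM. Floors and intervals cover counting error only. The 10 most abundant genes took 9.31% to 13.2% of counts, and mitochondrial genes 2.35% to 2.50%. No pair of replicates agreed within sampling noise: chi-square over its degrees of freedom was 126 for the PBS pair and 43.6 to 82.7 among the IL-10/Fc pairs. This argues against 1 library sequenced again under another name. It cannot tell whether libraries came from different mice, since amplification also adds spread. Every library was counted as 1 replicate.

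Genes were kept with edgeR's filterByExpr by group, which left 15477. Counts were scaled by TMM, with factors of 1.10 and 1.06 in PBS and 0.950 to 0.983 in IL-10/Fc, and tested with edgeR's quasi-likelihood test (glmQLFit with the robust option, glmQLFTest) with group as the sole term, followed by Benjamini-Hochberg adjustment at 0.05. All tests were two-sided. A standard error was computed as the log2 fold change divided by the root of the F statistic. Values per group are means ± SD of TMM-scaled CPM. The estimated biological coefficient of variation was 0.543.

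The design, the alternatives, 37 gene lists, 21 single genes and the rule for naming genes were fixed before the data were examined. The rule took, among genes past the threshold with a log2 fold change of at least 1, a mean of at least 20 CPM, a named symbol (no numbered gene models or pseudogenes) and groups that did not overlap, up to 12 per direction. Where fewer than 5 passed in a direction, as here in both, the 5 with the smallest p at that CPM minimum and with a named symbol were named and said not to have passed. It added up to 4 members with the smallest p of each list described, and the 21 fixed genes, 78 genes in all. Other genes named as calls of a list or as single features were chosen after their values were seen.

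The 33 lists with 5 or more measured genes were tested with camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over the lists. The 4 lists of respiratory complexes were also tested as their union, a family of 1 test whose adjusted p equals its p. For each list, genes were counted past 0.05 adjusted over all genes and adjusted over the list alone. Alternatives tried were DESeq2 size factors, the DESeq2 Wald test, limma-voom, no count filter, a filter of 20 CPM in 2 libraries, no robust option, the replicate number as a block, and each library left out in turn. Scaling by library size only, the DESeq2 refit set beside the authors' table and that refit without each library were chosen after seeing the data. Without a PBS library, the remaining one was assumed to vary like the IL-10/Fc libraries. With the block, IL-10/Fc replicates 3 and 4 had no PBS library of the same number. The group difference then rested on replicates 1 and 2 of each group. The block used up nearly all residual degrees of freedom, so few genes could pass there whatever the pairing.

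The tests were tested on data simulated from the means, edgeR's dispersions and the sizes of these libraries, 2 against 4. Of 15477 genes, 200 with a mean of at least 20 CPM were changed. Of 100 genes changed 2-fold, edgeR recovered 28, limma-voom 30 and DESeq2 70. Of 100 changed 4-fold, they recovered 85, 84 and 96. Among unchanged genes edgeR called 9, limma-voom 5 and DESeq2 80. A shifted list was recovered by each test and none of the other lists was called. Genes were drawn independently, so this cannot show how the list tests behave where genes vary together. Correlations estimated in the real lists reached 0.553, for mitosis. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9.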

Results

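The transcriptome of terminally exhausted CD8+ T cells was measured in mouse melanomas exposed to interleukin-10 (IL-10) or to buffer. PMEL T cells, which bear a transgenic receptor for the melanocyte antigen gp100, were given intravenously as naive Thy1.1+ cells to C57BL/6 mice after total body irradiation with 4 Gy. The animals were then inoculated with B16F10 melanoma cells, a line that carries this antigen. On day 10 of tumour growth, activated Thy1.2+ PMEL cells were transferred, and 4 injections beside the tumour were started, of either phosphate-buffered saline (PBS) or 20 µg of IL-10/Fc, a fusion of the cytokine to an antibody Fc part. On day 18, Thy1.1+ cells bearing PD-1 and TIM-3, a surface pair that marks terminal exhaustion, were sorted at 500 cells per library and sequenced after Smart-Seq2 amplification. There were 2 PBS and 4 IL-10/Fc libraries. The deposited counts of 15898 genes summed to 26738871 and 28774401 in the PBS libraries and to 31227321, 29978621, 28235203 and 36941814 in the IL-10/Fc libraries.

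Trbv14, the V segment of the transgenic PMEL receptor, took 99.3% ± 0.0640 (SD, n = 2) of all counts on T cell receptor beta V genes in PBS and 98.8% ± 0.518 (SD, n = 4) in IL-10/Fc. Across genes, log2 CPM correlated at 0.912 between the PBS libraries, at 0.902 to 0.926 among the IL-10/Fc libraries and at 0.895 to 0.909 between groups. Genes are not independent replicates in these values. The first principal component held 25.9% of the variance and separated the groups.

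The comparison asked how IL-10/Fc altered the expression programme of terminally exhausted cells. Cells from IL-10/Fc-treated tumours carried more transcript of the cytolytic protease granzyme B (Gzmb), 3639 ± 848 CPM (SD, n = 4) against 652 ± 97.8 CPM (SD, n = 2), and more of the surface antigen Sca-1 (Ly6a), 4191 ± 409 CPM (SD, n = 4) against 748 ± 299 CPM (SD, n = 2). Genes of the interferon response, the T cell receptor complex and the cytotoxic machinery lay higher as groups, and those of DNA replication, mitosis and the tricarboxylic acid (TCA) cycle lay lower, by a test with a preset correlation between genes. Markers of macrophages and natural killer (NK) cells were also higher in the IL-10/Fc libraries. None of these 8 lists passed camera when the correlation was estimated from the libraries, with adjusted p from 0.492 to 0.734. That test lost power even where the estimated correlation was low, so the loss cannot be laid to correlated genes alone. Of single genes, only the interferon-induced Ifi27 passed edgeR's test across all genes, at 614 ± 23.4 CPM (SD, n = 4) against 255 ± 2.51 CPM (SD, n = 2), and it passed in only some of the other settings.

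By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Ifi27 rose with a log2 fold change of 1.27 (SE 0.09, adjusted p = 0.0484), and no other gene of 15477 passed. Without single libraries its log2 fold change stayed between 1.25 and 1.29, but it passed only when PBS replicate 2 was the one left out (adjusted p = 0.045). It also missed the threshold without the robust option (adjusted p = 0.0746), with the replicate number as a block (adjusted p = 0.612) and with scaling by library size only (log2 fold change 1.10, adjusted p = 0.118). At an unadjusted p under 0.05 there were 1970 genes, 1115 higher and 855 lower, where chance gives 774. Limma-voom had 2030 at that cut, with most of them lower (943 higher and 1087 lower), and DESeq2 had 2520, 1503 higher and 1017 lower. The authors' deposited table called 842 genes at an adjusted p under 0.05, 568 higher and 274 lower in IL-10/Fc. DESeq2 fitted to the same counts called 738 genes, 502 higher and 236 lower, and 728 of these were called in the authors' deposited table as well. Limma-voom called 1 gene. The 2 PBS libraries and the 4 IL-10/Fc libraries did not overlap for 3651 genes, 23.6% of those tested, where chance gives 13.3%.

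Among genes with a named symbol (no numbered gene models) and a mean of at least 20 CPM, the 4 with the next smallest p on the higher side were Gzmb, Ly6a, Cd2 and Tagln2. Gzmb (chromosome 14, 56258856 to 56262260 in GRCm38) had a log2 fold change of 2.48 (SE 0.25) and Ly6a (chromosome 15, 74994877 to 74998031) of 2.49 (SE 0.26). Cd2 (chromosome 3, 101275899 to 101287939), an adhesion and costimulatory receptor of T cells, stood at 1026 ± 179 CPM (SD, n = 2) in PBS and 2427 ± 131 CPM (SD, n = 4) in IL-10/Fc. Tagln2 (chromosome 1, 172500047 to 172507380), an actin-binding protein, stood at 708 ± 29.5 and 1291 ± 91.5 CPM, and Ifi27 itself lies on chromosome 12 at 103434211 to 103440239. None of these 4 passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, with adjusted p from 0.141 to 0.148. With the filter of 20 CPM in 2 libraries all 4 passed, with adjusted p from 0.0179 to 0.0382. In the authors' deposited table all 4 were called higher, Gzmb with an adjusted p of 5.55e-20.

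No gene passed as lower by edgeR's test across all 15477 genes. Those with the smallest p among the lower genes, within the same limits, were Lancl1, Phgdh, Itgb1, Dusp1 and Mxd4, each at an adjusted p of 0.148 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Itgb1 (chromosome 8, 128685654 to 128733200), the integrin beta-1 chain, stood at 339 ± 71.9 CPM (SD, n = 2) in PBS and 89.8 ± 20.9 CPM (SD, n = 4) in IL-10/Fc, a log2 fold change of -1.92 (SE 0.24). Dusp1 (chromosome 17, 26505590 to 26508519), a phosphatase of MAP kinases, stood at 559 ± 83.6 and 188 ± 44.0 CPM. Phgdh (chromosome 3, 98313170 to 98339990), which catalyses the first committed step of serine synthesis, stood at 96.4 ± 3.94 and 52.8 ± 2.74 CPM. Lancl1 (chromosome 1, 67000517 to 67038872) had a log2 fold change of -1.17 and Mxd4 (chromosome 5, 34173883 to 34187720), a member of the MAX-binding MXD repressors, of -1.20. With the filter of 20 CPM in 2 libraries all 5 passed (adjusted p from 0.0264 to 0.0413). The authors' deposited table called all 5 lower.

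**Figure D1:**
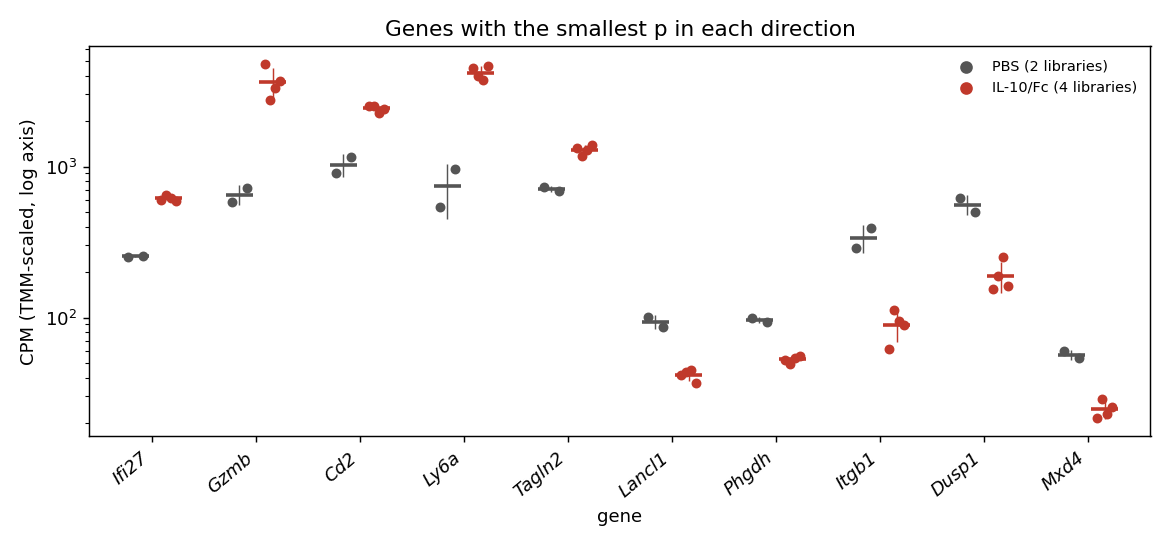
Expression of the 5 named genes with the smallest p in each direction at a mean of at least 20 CPM, in CPM scaled by TMM on a log axis; points are libraries (2 PBS in grey, 4 IL-10/Fc in red), thick lines group means and thin lines 1 SD. For every gene drawn the groups do not overlap, as for Gzmb, with 583 and 721 CPM in PBS and at least 2763 CPM in each IL-10/Fc library.

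The interferon response list, 31 genes induced by interferons, had a median log2 fold change of 0.72 and 29 of its genes lay higher. By camera with a preset correlation its adjusted p was 4.23e-07, and the adjusted p = 0.492 with an estimated correlation. None of its genes passed over all genes tested, and 4 passed higher when adjusted over the list alone, Ly6a, Zbp1, Rtp4 and Ifi35. Zbp1, a sensor of Z-form nucleic acids, stood at 60.5 ± 28.2 CPM (SD, n = 2) in PBS and 230 ± 45.4 CPM (SD, n = 4) in IL-10/Fc, and Rtp4 at 21.2 ± 6.92 and 72.1 ± 18.5 CPM. The authors' deposited table called 7 of the 31 higher and none lower. Without PBS replicate 2 the median was 1.16. Macrophage and NK markers, described further on, were higher in the same libraries.

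The T cell receptor complex list, 17 genes of the receptor, its coreceptors and its proximal signalling, had a median log2 fold change of 0.51, with 14 genes higher. Its adjusted p was 2.1e-04 by camera with a preset correlation, and the adjusted p = 0.492 with an estimated correlation. Over all genes tested 0 passed, and 7 passed higher when adjusted over the list alone, namely Cd2, Ptprc, Cd3d, Thy1, Lat, Cd3g and Cd8b1. Ptprc, which encodes the phosphatase CD45, stood at 834 ± 34.5 CPM (SD, n = 2) in PBS and 1514 ± 147 CPM (SD, n = 4) in IL-10/Fc, and Cd3d at 1434 ± 66.6 and 2327 ± 211 CPM. Thy1 and CD8 were also markers of the sort. The same 7 genes were called higher in the authors' deposited table, and none lower.

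The cytotoxic effector list, 20 genes of granzymes, granule proteins and death ligands, had a median log2 fold change of 0.60, with 15 genes higher and 5 lower. Camera with a preset correlation gave an adjusted p of 0.0146, and the adjusted p = 0.492 with an estimated correlation. None passed over all genes tested, and Gzmb, Srgn and Ctsw passed higher when adjusted over the list alone. The proteoglycan of cytotoxic granules, Srgn, stood at 2427 ± 411 CPM (SD, n = 2) in PBS and 3487 ± 184 CPM (SD, n = 4) in IL-10/Fc. Ctsw, a cysteine protease of cytotoxic cells, stood at 794 ± 182 and 1291 ± 166 CPM, and the granule membrane protein gene Nkg7 at 7065 ± 3015 and 13115 ± 1092 CPM. The authors' deposited table called these 4 genes higher and no gene of the list lower. Without PBS replicate 2 the list's median was 0.16 (camera, adjusted p = 0.252), and without IL-10/Fc replicate 1 it was 0.51 (adjusted p = 0.052). With the replicate number as a block it was 0.33 (adjusted p = 0.189).

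The macrophage and monocyte list, 18 markers of cells outside the gate, had a median log2 fold change of 1.52, with 16 genes higher. By camera with a preset correlation the adjusted p was 9.64e-04, and the adjusted p = 0.492 with an estimated correlation. With the replicate number as a block the median was 0.55 (camera adjusted p = 0.143). None passed over all genes or when adjusted over the list alone. Ly6c2 held most of the counts, at 1686 ± 689 CPM (SD, n = 2) in PBS and 4736 ± 1864 CPM (SD, n = 4) in IL-10/Fc; activated CD8+ T cells express it too, and its reads are hard to tell from those of Ly6c1. Fcer1g, an adaptor of Fc receptors, stood at 37.6 ± 4.46 and 228 ± 132 CPM, the lysosomal glycoprotein gene Cd68 at 43.0 ± 6.08 and 85.8 ± 21.6 CPM, and Ms4a7 at 1.55 ± 1.47 and 14.8 ± 9.59 CPM. The authors' deposited table called 5 of the 18 higher, these 4 and the mannose receptor gene Mrc1. The latter was at 0 in both PBS libraries and at 2.81 ± 2.50 CPM (SD, n = 4) in IL-10/Fc, at least 25-fold higher against a floor of 3 counts per library.

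The NK list of 8 genes, of which Fcer1g and Tyrobp are also in the macrophage list, had a median log2 fold change of 1.5 and a mean of 0.80, with 6 genes higher. Camera with a preset correlation gave an adjusted p of 0.0288, and the adjusted p = 0.492 with an estimated correlation. None passed over all genes tested, and Fcer1g alone passed when adjusted over the list alone. The receptor gene Klra8 stood at 0.299 ± 0.0389 CPM (SD, n = 2) and 2.82 ± 1.94 CPM (SD, n = 4), and Klra9 at 2.28 ± 1.05 and 10.4 ± 7.12 CPM; the Klra genes are near-identical in part, so their counts are uncertain. Klrb1c, at 10.1 and 0.07 CPM in the PBS libraries, lay below 1 CPM in each IL-10/Fc library. Without PBS replicate 2 the list's adjusted p was 0.173 by camera. With the replicate number as a block the median was 0.85 (adjusted p = 0.189), and at 20 CPM or more in 2 libraries 4 genes were left, with a median of 0.99.

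Counts on 8 listed dendritic cell and MHC class II genes summed to 274 ± 65.2 CPM (SD, n = 2) in PBS and 937 ± 737 CPM (SD, n = 4) in IL-10/Fc, from 172 CPM in IL-10/Fc replicate 1 to 1915 CPM in replicate 3. That list was not called (median log2 fold change 2.11, camera adjusted p = 0.416), and its median was -0.07 with the replicate number as a block. Melanoma markers summed to 13.5 ± 5.58 and 19.0 ± 6.85 CPM, and the list had a median of 1.21 (camera adjusted p = 0.142), at 0.54 without PBS replicate 1 and 2.47 without PBS replicate 2. B cell markers summed to 59.1 ± 15.5 and 27.7 ± 17.0 CPM, neutrophil markers to 1.55 ± 0.349 and 4.44 ± 1.62 CPM, and the 2 listed fibroblast and endothelial markers to 18.5 ± 2.67 and 7.99 ± 1.53 CPM. Markers of CD4 and regulatory T cells summed to 1590 ± 218 and 1368 ± 221 CPM, mostly on genes that exhausted CD8+ T cells also express, and that list had a median of 0.07 (camera adjusted p = 0.998), at -0.58 without PBS replicate 2. No red blood cell marker was among the listed genes.

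Proliferation genes lay lower in IL-10/Fc by list medians, while the libraries overlapped. The mean log2 CPM of DNA replication genes was 5.19 and 5.44 in PBS and 4.82, 4.80, 5.33 and 5.06 in IL-10/Fc replicates 1 to 4, and that of mitosis genes 5.26 and 4.83 against 4.12, 4.35, 5.23 and 4.83. The DNA replication list had a median log2 fold change of -0.36, with 34 of 39 genes lower. By camera with a preset correlation its adjusted p was 0.00337, and the adjusted p = 0.631 with an estimated correlation. The mitosis list had a median of -0.37, with 28 of 37 genes lower, an adjusted p of 0.00724 by camera with a preset correlation, and the adjusted p = 0.734 with an estimated correlation. In both lists 0 genes passed over all genes, and 0 when adjusted over the list alone. The replicative helicase subunit gene Mcm5 stood at 77.0 ± 9.25 CPM (SD, n = 2) in PBS and 46.7 ± 4.76 CPM (SD, n = 4) in IL-10/Fc, Mcm7 at 116 ± 14.4 and 72.7 ± 15.9 CPM, and Lig1, the DNA ligase of replication, at 79.8 ± 8.18 and 51.8 ± 13.6 CPM. The polymerase gene Pola1 went the other way, at 15.7 ± 8.61 and 28.6 ± 3.51 CPM. Aurkb, a mitotic kinase, stood at 66.2 ± 1.79 and 33.0 ± 10.3 CPM, Cenpa at 368 ± 12.1 and 237 ± 66.8 CPM, Ndc80 at 66.5 ± 3.47 and 49.6 ± 4.50 CPM and Ttk at 15 ± 3.94 and 6.93 ± 3.94 CPM. Mcm5 was the only gene of either list called in the authors' deposited table, where it was lower. The proliferation marker Mki67 had a log2 fold change of 0.11 (SE 0.33), which turned to -0.06 with scaling by library size only. Without PBS replicate 2 the DNA replication median was -0.18 (camera adjusted p = 0.271). The mitosis list passed neither without PBS replicate 1 (median -0.12, adjusted p = 0.373) nor without IL-10/Fc replicates 1 (adjusted p = 0.107) or 2 (adjusted p = 0.1). With the replicate number as a block the medians were larger, -0.51 for DNA replication (camera adjusted p = 4.8e-05) and -0.80 for mitosis (camera adjusted p = 2.17e-07). The block took IL-10/Fc replicates 3 and 4, which had the higher means of both lists, out of the group difference. With scaling by library size only the medians were -0.53 for both (camera adjusted p = 0.00222 and 0.0123).

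Metabolic lists differed in direction. The TCA cycle list had a median log2 fold change of -0.17, with 18 of 21 genes lower, and an adjusted p of 0.0136 by camera with a preset correlation. Its adjusted p = 0.492 with an estimated correlation, and without PBS replicate 1 camera with the preset correlation gave 0.0511. It also missed the threshold with at least 20 CPM in 2 libraries (adjusted p = 0.0749) and with the replicate number as a block (median -0.24, adjusted p = 0.0615), and without PBS replicate 2 the median was -0.32 (adjusted p = 0.0452). With scaling by library size only it was -0.34 (adjusted p = 0.00222). No gene of it passed over all genes or when adjusted over the list alone. The mitochondrial isocitrate dehydrogenase gene Idh2 stood at 13.2 ± 0.156 CPM (SD, n = 2) in PBS and 6.18 ± 1.20 CPM (SD, n = 4) in IL-10/Fc, and was the 1 gene of the list called lower in the authors' deposited table. Suclg2, a subunit of succinate-CoA ligase, stood at 47.0 ± 19.3 and 20.7 ± 7.97 CPM.

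The 82 nuclear-encoded genes of oxidative phosphorylation had a median log2 fold change of 0.13, with 57 higher and 25 lower. By camera with a preset correlation its adjusted p was 0.0126, and the adjusted p = 0.341 with an estimated correlation. With scaling by library size only, which moved the median of all genes by -0.17, the list's median turned to -0.04 (camera adjusted p = 0.46). No gene passed over all genes or when adjusted over the list alone, and the authors' deposited table called 6 higher and 4 lower. Cox5a, a subunit of complex IV, stood at 402 ± 0.807 CPM (SD, n = 2) in PBS and 625 ± 61.3 CPM (SD, n = 4) in IL-10/Fc, a log2 fold change of 0.64 (SE 0.12). Atp5b, the catalytic beta subunit of ATP synthase, stood at 1812 ± 23.9 and 1329 ± 82.5 CPM, a log2 fold change of -0.45 (SE 0.09). Without PBS replicate 2 camera gave an adjusted p of 0.168, without IL-10/Fc replicate 4 an adjusted p of 0.0634, and with the replicate number as a block an adjusted p of 0.139. By complex, the medians were 0.13 for complex I, -0.05 for complexes II and III, 0.24 for complex IV and 0.11 for ATP synthase, and no complex was called. Without PBS replicate 2 the medians were -0.22 for complexes II and III, 0.13 for complex IV and 0.04 for ATP synthase, and without PBS replicate 1 they were 0.07 for complexes II and III and 0.19 for ATP synthase. Complexes I and IV passed with limma-voom (camera adjusted p = 0.0017 for each) and with DESeq2 (adjusted p = 0.0197 and 0.00879). When adjusted over each of these lists alone, Cox5a, Cox8a and Cox7b of complex IV passed higher, and 3 genes of ATP synthase passed higher and 2 lower, Atp5b among the latter. Those of complex I and ATP synthase turned negative with scaling by library size only, at -0.04 and -0.06. The 9 mitochondrially encoded subunits had a median of 0.12 (camera adjusted p = 0.131), which turned to -0.05 with that scaling and passed with limma-voom (adjusted p = 0.00509), and share reads with nuclear pseudogene copies.

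The pyruvate entry list, which holds the mitochondrial pyruvate carrier, the pyruvate dehydrogenase complex and its kinases, had a median of -0.25 and was not called (camera adjusted p = 0.0742). With scaling by library size only it passed, at -0.42 (camera adjusted p = 0.041), as it did without PBS replicate 2, at -0.37 (adjusted p = 0.0183), while without PBS replicate 1 the median was -0.11 (adjusted p = 0.655). The carrier genes Mpc1 and Mpc2 stood at 102 ± 27.9 and 129 ± 17.3 CPM (SD, n = 2) in PBS and at 96.4 ± 8.89 and 138 ± 5.32 CPM (SD, n = 4) in IL-10/Fc. Their log2 fold changes of -0.08 (SE 0.18) and 0.10 (SE 0.11) were within the spread between libraries. The kinase genes Pdk1 and Pdk2 stood at 25.2 ± 7.24 and 2.13 ± 1.02 CPM in PBS and at 15.5 ± 6.50 and 0.704 ± 0.268 CPM in IL-10/Fc. Glycolysis genes had a median of -0.08 (camera adjusted p = 0.998), which turned to 0.08 without PBS replicate 1. Among them Hk2, a hexokinase, stood at 22.1 ± 7.71 and 50.7 ± 11.3 CPM and was called higher in the authors' deposited table. The glucose transporter gene Slc2a1 stood at 77.2 ± 11.5 and 68.9 ± 9.82 CPM. Genes of fatty acid oxidation had a median of -0.29 (camera adjusted p = 0.187), at -0.08 without PBS replicate 1. Those of cholesterol synthesis had a median of -0.03 and a mean of 0.03 (camera adjusted p = 0.417), at -0.29 without PBS replicate 1 and 0.02 without IL-10/Fc replicate 1.

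**Figure D2:**
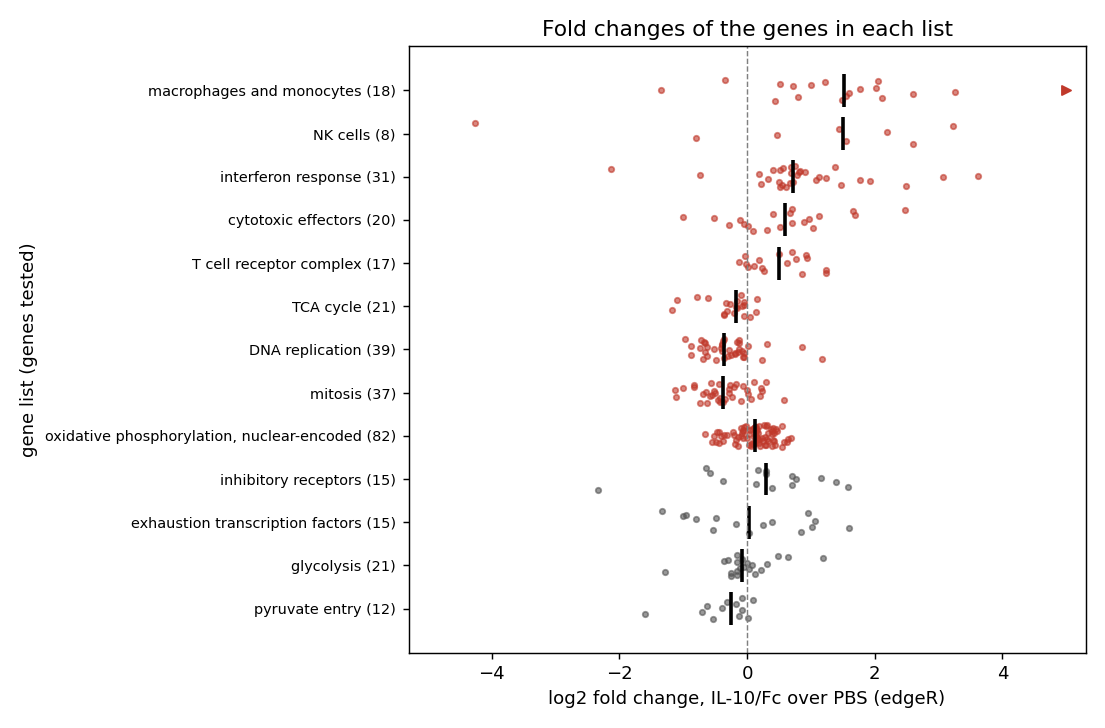
Log2 fold changes of single genes (edgeR, IL-10/Fc over PBS) in 13 lists, with the number of genes tested in brackets; points are genes, black lines list medians, red marks lists past the preset-correlation test and grey marks lists that were not. The triangle is 1 gene beyond the axis limit of 5, Mrc1, which had no count in PBS; medians run from 1.52 for macrophage markers to -0.37 for mitosis.

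Inhibitory receptors, which mark exhaustion, had a median log2 fold change of 0.30 over 15 genes and were not called (camera adjusted p = 0.0866). The list passed without PBS replicate 2, at 0.51 (adjusted p = 0.0182), and with limma-voom (adjusted p = 0.0202). Cd160 stood at 206 ± 66.6 CPM (SD, n = 2) in PBS and 459 ± 23.7 CPM (SD, n = 4) in IL-10/Fc, and was the 1 gene of the list that passed higher when adjusted over the list alone. The authors' deposited table called Cd160 higher and Cd200r1 lower. Transcripts of the sort markers were at 1432 ± 207 and 918 ± 177 CPM for Pdcd1, which encodes PD-1, and at 194 ± 8.06 and 219 ± 64.4 CPM for Havcr2, which encodes TIM-3. Lag3 stood at 105 ± 21.1 and 129 ± 10.3 CPM, Tigit at 231 ± 48.2 and 155 ± 45.9 CPM, and Entpd1, the ectonucleotidase CD39, at 217 ± 114 and 370 ± 28.1 CPM. None of these 5 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p from 0.285 to 0.856. The NK receptor gene Klrc1 stood at 1884 ± 252 and 2459 ± 95.1 CPM.

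Exhaustion transcription factors had a median of 0.03 (camera adjusted p = 0.796), which turned to -0.13 with scaling by library size only, to -0.34 with at least 20 CPM in 2 libraries and to -0.21 without PBS replicate 1, and was 0.32 without PBS replicate 2. Tox, a driver of the exhausted state, stood at 33.1 and 481 CPM in the PBS libraries and between 20.1 and 181 CPM in the IL-10/Fc libraries. Tcf7, the factor of stem-like T cells, stayed at or below 12.1 CPM in each library. Id2 stood at 870 ± 340 CPM (SD, n = 2) and 1569 ± 200 CPM (SD, n = 4), and Prdm1 at 11.8 ± 3.21 and 23.9 ± 5.99 CPM. The authors' deposited table called these 2 higher and the orphan receptor gene Nr4a2 lower. Stem-like and memory genes had a median of 0.14 and a mean of -0.10 (camera adjusted p = 0.468). That median rested on the PBS libraries, at 1.16 without PBS replicate 1, where the list passed (adjusted p = 0.0448), and at -0.42 without PBS replicate 2 (adjusted p = 0.311), and it was -0.02 with scaling by library size only. In the list 2 genes passed when adjusted over the list alone. One was Ccr7, the lymph node homing receptor, at 4010 and 548 CPM in the PBS libraries against 147 ± 57.2 CPM (SD, n = 4) in IL-10/Fc. The other was the chromatin organiser gene Satb1, at 39.7 ± 16.8 CPM (SD, n = 2) and 137 ± 48.2 CPM (SD, n = 4).

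Il10ra, the ligand-binding chain of the IL-10 receptor, stood at 60.8 ± 25 CPM (SD, n = 2) in PBS and 17.1 ± 3.90 CPM (SD, n = 4) in IL-10/Fc, a log2 fold change of -1.83 (SE 0.31). It missed the threshold over all genes (adjusted p = 0.158 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With the filter of 20 CPM in 2 libraries it passed lower by that test (log2 fold change -1.855, adjusted p = 0.04225). It also passed lower when adjusted over its list alone, and was called lower in the authors' deposited table. Its partner chain Il10rb stood at 32.8 ± 3.16 and 34.9 ± 6.61 CPM. Stat3, the transcription factor downstream of the receptor, stood at 347 ± 171 and 253 ± 18.8 CPM, and its feedback target Socs3 at 2.32 ± 0.926 and 4.79 ± 3.79 CPM. The IL-10 and STAT3 response list had a median of 0.49 (camera adjusted p = 0.158), which fell to 0.07 (adjusted p = 0.598) with at least 20 CPM in 2 libraries. Mcl1, Pim1 and Jak1 passed higher when adjusted over that list alone, and the survival factor gene Mcl1 stood at 60.5 ± 4.06 and 103 ± 8.07 CPM.

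Effector cytokines and chemokines had a median of 0.30 (camera adjusted p = 0.141), at 0.14 without IL-10/Fc replicate 1, 0.74 without PBS replicate 1, 0.76 with at least 20 CPM in 2 libraries and 0.13 with scaling by library size only. Ifng stood at 193 and 1424 CPM in the PBS libraries and between 1347 and 3774 CPM in the IL-10/Fc libraries, and Tnf at 26.0 ± 4.10 CPM (SD, n = 2) and 21.8 ± 8.52 CPM (SD, n = 4). Prf1, the gene of perforin, stood at 354 ± 240 and 695 ± 73.6 CPM, and Cd8a at 1601 ± 977 and 3075 ± 122 CPM. Of the chemokines, Ccl5 stood at 3840 ± 1894 and 8924 ± 1412 CPM and Ccl4 at 233 ± 206 and 740 ± 133 CPM; both were called higher in the authors' deposited table. T cell activation markers had a median of -0.03 and a mean of 0.06 (camera adjusted p = 0.436), with the median at 0.30 without PBS replicate 1 (adjusted p = 0.0511) and at 0.21 with limma-voom. Among them the costimulatory receptor gene Icos stood at 1114 ± 205 and 2252 ± 182 CPM and passed higher when adjusted over the list alone, while Tnfrsf18 stood at 710 ± 160 and 535 ± 16.9 CPM.

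**Figure D3:**
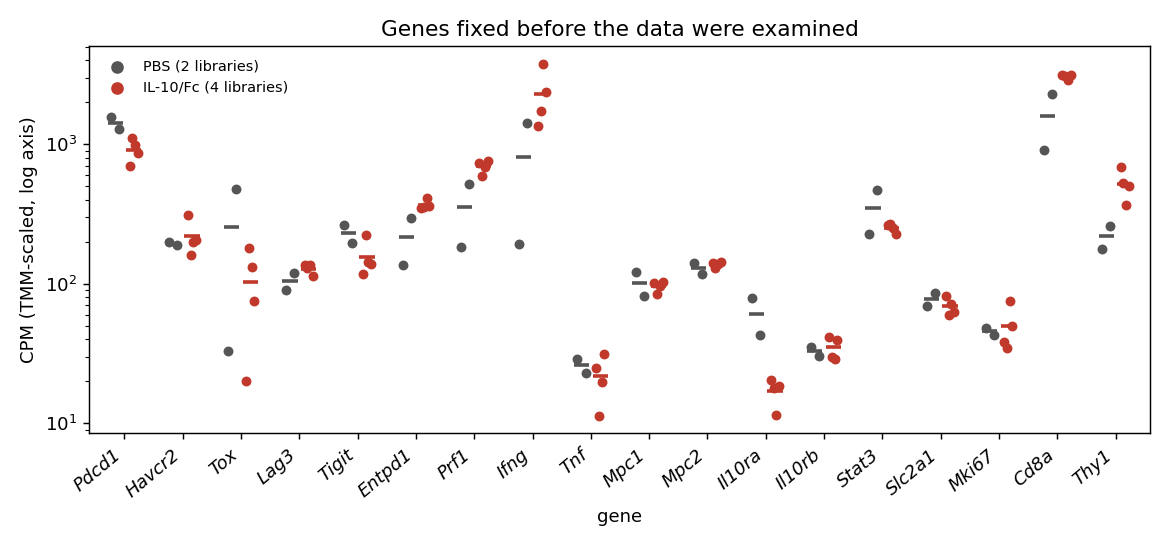
CPM, scaled by TMM and on a log axis, of 18 of the 21 genes fixed before the data were examined; points are libraries (2 PBS in grey, 4 IL-10/Fc in red) and lines group means, with no error bars. The PBS libraries lie far apart for Tox, at 33.1 and 481 CPM, and for Ifng, at 193 and 1424 CPM.

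Antigen presentation by MHC class I had a median of 0.17 (camera adjusted p = 0.0742). It passed without PBS replicate 2, at 0.26 (adjusted p = 0.0182), with limma-voom (adjusted p = 0.0132) and with DESeq2 (adjusted p = 0.0436), while the median was 0.08 without PBS replicate 1 and 0.01 with scaling by library size only. B2m, its invariant light chain, stood at 8385 ± 1646 CPM (SD, n = 2) and 13129 ± 1161 CPM (SD, n = 4), and the immunoproteasome subunit gene Psmb10 at 259 ± 64.5 and 426 ± 39.0 CPM. These 2 passed higher when adjusted over the list alone. Genes of the cytosolic ribosome had a median of -0.05 (camera adjusted p = 0.142), and with scaling by library size only they passed at -0.23 (adjusted p = 0.00117). They also passed without PBS replicate 2 (median -0.11, adjusted p = 0.0226), with limma-voom (adjusted p = 0.0277) and with DESeq2 (adjusted p = 0.00919), and the median was 0.00 without PBS replicate 1. Rpl3 passed lower when adjusted over the list alone. Medians of the remaining lists were 0.00 for the mitochondrial ribosome, 0.02 for the proteasome, 0.05 for apoptosis regulators, 0.15 for the unfolded protein response and -0.05 for heat shock and dissociation stress. None of these was called, with adjusted p by camera from 0.167 to 0.998. When adjusted over the list alone, Mcl1 and Casp9 of the apoptosis regulators passed higher, Casp9 at 0 in both PBS libraries, and Dusp1 of the heat shock list passed lower. With scaling by library size only, those of the mitochondrial ribosome (-0.17), the proteasome, the apoptosis regulators and the unfolded protein response turned negative. The unfolded protein response stood at 0.01 without PBS replicate 1 and 0.42 without PBS replicate 2, the heat shock list turned to 0.12 and 0.16 without these, and the apoptosis regulators stood at 0.19 without PBS replicate 1.

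In total 8 of 33 lists passed camera with a preset correlation, 5 higher and 3 lower. None of them passed with an estimated correlation and none by fry's directional test, while 15 passed fry's test for change in either direction. Estimating the correlation raised camera's unadjusted p even where the estimate was low. For effector cytokines and chemokines, at -0.0258, it went from 0.0639 to 0.118. For cytotoxic effectors, at 0.0264, it went from 0.00309 to 0.0579. With scaling by library size only, 10 lists passed, 5 higher and 5 lower. With single libraries left out, edgeR called 0 genes without PBS replicate 1 or without IL-10/Fc replicates 2, 3 or 4, 1 gene other than Ifi27 without IL-10/Fc replicate 1, and 16 genes without PBS replicate 2. In DESeq2 refits the count was 511 without PBS replicate 1, 1155 without PBS replicate 2 and 464 without IL-10/Fc replicate 4.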

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

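Tests of a PBS library set apart, of the share of T cells, of monocyte RNA and of RNA of antigen-presenting cells were chosen after the results were seen; those of other groupings and of GC content and length were planned before. Among 113 items examined within the 4 IL-10/Fc libraries, 8 had 1 library far from the others by Dixon's ratio of gap to range, above its 95% critical value. Chance gives such a library in about 1 in 20 groups, or 5.65 of 113.

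IL-10/Fc replicate 1 stood apart for 4 genes. Satb1 was at 209 CPM there against 111 to 117 in the others (ratio 0.945), Ccr7 at 232 against 108 to 129 CPM (0.834), Srgn at 3760 against 3372 to 3431 CPM (0.848), and Idh2 at 4.39 against 6.59 to 6.95 CPM (0.859). Replicate 3 stood apart for the helicase gene Mcm7, at 96.4 against 63.6 to 67.2 CPM (0.891), and for T cell activation markers, with a mean log2 CPM of 7.62 against 7.47 to 7.49 (0.839). Replicate 4 stood apart for Lig1, at 72.1 against 42.9 to 47.0 CPM (0.861), and for complex I, with a mean log2 CPM of 7.62 against 7.51 to 7.53 (0.899).

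Genes of the interferon response, the T cell receptor complex and the cytotoxic machinery together had a median log2 fold change of 0.68 over 68 genes. The 95% intervals in this paragraph treat genes as independent and may be too narrow. Correlations between genes estimated within these lists were 0.196, 0.296 and 0.0264. A single odd PBS library is argued against as the whole cause, since the median stayed at 0.605 without PBS replicate 1 (95% interval 0.451 to 0.897) and at 0.823 without PBS replicate 2. For the cytotoxic list alone it stays open, as that list's median was 0.157 without PBS replicate 2. A trend with GC content or length is argued against as well. It was removed for genes at a mean of 1 CPM or more, which covered 66 genes of the 3 lists. Their median was 0.684 before the removal and 0.643 after it (0.491 to 0.762). A lower share of T cells in the PBS libraries would place markers of other cells higher there. The 38 markers of melanoma, myeloid, dendritic, neutrophil, B and stromal cells, of which 18 are macrophage markers, had a median log2 fold change of 1.33 (0.718 to 2.02) towards IL-10/Fc. Ighm and Pecam1 did lie higher in PBS, Ighm at 42.3 ± 0.264 CPM (SD, n = 2) against 5.66 ± 4.92 CPM (SD, n = 4) and Pecam1 at 18.5 ± 2.70 against 7.68 ± 1.74 CPM, and the other B cell markers shared no direction. Summed over their markers, B cells (59.1 against 27.7 CPM) and fibroblasts and endothelium (18.5 against 7.99 CPM) were higher in PBS. Melanoma, macrophage, dendritic and neutrophil markers were higher in IL-10/Fc by their sums. The macrophage list was already known to lie higher when this test was chosen, so the median cannot decide on the share of T cells. The receptor genes Trbc2 and Trbv14 lay slightly lower in PBS. Each had a log2 fold change of 0.23 (SE 0.10 and 0.11), with overlapping libraries. A T cell share lowered in PBS, as by B or stromal cells, stays open, as does a change in the cell types that rose. An effect of IL-10/Fc on the T cells may remain, as a hypothesis found and tested on the same libraries, beside unrecorded differences between mice or sorts.

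Ly6c2, a monocyte marker that activated CD8+ T cells also express, lay 3050 CPM higher in IL-10/Fc. Monocyte RNA is argued against as its source, since Lyz2, an abundant transcript of monocytes, differed by -36.8 CPM, at 40.3 and 301 CPM in PBS and 32.1 to 185 CPM in IL-10/Fc. Expression by the T cells may account for it, and reads shared with Ly6c1 leave open which of these genes was measured.

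The other macrophage markers followed a different course. Within the 4 IL-10/Fc libraries, the 16 markers other than Ly6c2 and Ccr2 had a median correlation of 0.90 with the mean of MHC class II genes. That median lay at percentile 100 of 10000 random gene sets matched on expression. Random sets were drawn gene by gene, whereas markers that vary together for any reason can reach such a rank. The percentile therefore does not tell the source of these markers. H2-Aa was at 23.7 CPM in replicate 1 and at 131, 425 and 213 CPM in replicates 2, 3 and 4, and C1qb at 12.3, 44.0, 98.3 and 129 CPM. The share of Trbv14 among beta V genes was 99.3% in replicate 1 and 99.1%, 98.2% and 98.5% in replicates 2, 3 and 4. That share concerns T cells only and does not count antigen-presenting cells. RNA of antigen-presenting cells that passed the sort may be the source of these markers. The gate for Thy1.1 and CD8 should remove most such cells, but a purity above 99% leaves room for a few. A change of these marker genes in the T cells stays open and was not tested.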

How the results depend on the processing

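Scaling by library size only and the refits behind the authors' count were chosen after the results were seen; the other settings were planned. The 8 called lists kept the sign of their medians in all refits, and of 78 named genes 69 kept theirs. Camera with an estimated correlation and fry used the main fit, so the medians could not differ there. The gene count of 1 became 738 with DESeq2, 60 (44 higher, 16 lower, all 60 called in the authors' deposited table) with at least 20 CPM in 2 libraries, where fewer genes were tested, and 0 without the robust option or with library size scaling only (edgeR). Without single libraries it was 0 to 16. Where 8 lists were called, 14 passed with limma-voom, 0 with an estimated correlation and 0 by fry. With the replicate number as a block, 0 genes and 4 lists passed, and the oxidative phosphorylation median was 0.12 (camera adjusted p = 0.139). Medians no longer past the threshold were 0.55 for macrophages, -0.24 for the TCA cycle, 0.33 for cytotoxic effectors and 0.85 for NK cells. DNA replication and mitosis grew to -0.51 and -0.80. IL-10/Fc replicates 3 and 4, which had the higher means of these 2 lists, did not enter the group difference there. The block left few degrees of freedom, and the labels do not state that equal numbers were paired. Missed thresholds there are therefore weak evidence. Deviations of same-numbered libraries correlated at 0.0625 and 0.0148 by the titles' numbers, and at -0.0148 and 0.0361 by the file columns' numbers. With 2 PBS libraries the deviations of 1 mirror those of the other, so these values cannot decide on pairing. Other causes of these shifts were not tested.

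The oxidative phosphorylation median was -0.040 with library size scaling only, 0.0892 to 0.151 without single libraries, and its 0.132 did not pass with an estimated correlation (adjusted p = 0.341) or by fry (adjusted p = 0.0576). By the same tests the lists' adjusted p were 0.492 and 0.105 for interferon response (median 0.718), T cell receptor complex (0.508), TCA cycle (-0.171) and NK cells (1.5), 0.492 and 0.201 for macrophages (1.52), 0.492 and 0.451 for cytotoxic effectors (0.598), 0.631 and 0.342 for DNA replication (-0.361), and 0.734 and 0.535 for mitosis (-0.369). With at least 20 CPM the TCA cycle stood at -0.180 (adjusted p = 0.0749) and the NK list had 4 genes, too few for its test, with a median of 0.99. Without single libraries medians ran from -0.406 to -0.185 for DNA replication, -0.502 to -0.124 for mitosis, -0.322 to -0.156 for the TCA cycle (-0.341 with library size scaling only), 0.157 to 0.825 for cytotoxic effectors and 1.25 to 1.88 for NK cells. The authors' 842 calls became 738 in the refit and 464 to 1155 without single libraries, with 511 without PBS replicate 1 and 464 without IL-10/Fc replicate 4, and 204 of the 842 were called in every one of these.

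Log2 fold changes of 9 named genes, none past a threshold, changed sign. Without single libraries they ran from -5.25 to 1.94 for Klrb1c, -2.05 to 1.57 for Tcf7 and -0.34 to 0.23 for Mpc1 (positive without PBS replicate 1), -2.24 to 1.63 for Tox and -0.89 to 0.16 for Stat3 (positive without PBS replicate 2), -0.034 to 0.24 for Mpc2 (negative there), -0.0062 to 0.19 for Il10rb (negative without PBS replicate 2 or IL-10/Fc replicate 1), -0.043 to 0.30 for Havcr2 (negative without IL-10/Fc replicate 1) and -0.165 to 0.25 for Mki67 (negative without IL-10/Fc replicate 3). With the replicate block Tcf7 was at 0.31 and Mki67 at -0.33, and with library size scaling only Mpc2 was at -0.077, Il10rb at -0.085 and Mki67 at -0.055. Klrb1c and Tcf7 were at or near 0 in some libraries.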

Other observations

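The families named here were chosen after their values were seen, and the tests of other groupings of the libraries were planned before. Members of the Ly6 family lay higher in IL-10/Fc, 9 of 9 with a median log2 fold change of 1.60, and 7 of them were called higher in the authors' deposited table. Ly6e stood at 1771 ± 393 CPM (SD, n = 2) in PBS and 3587 ± 307 CPM (SD, n = 4) in IL-10/Fc, Ly6c1 at 283 ± 94.3 and 854 ± 285 CPM, and Ly6i at 3.0 ± 1.99 and 15.2 ± 6.87 CPM. Ly6k was at 0 in both PBS libraries and at 3.62, 0.07, 0.68 and 18.4 CPM in the IL-10/Fc libraries. Of the Ms4a family 8 of 9 lay higher, with a median of 0.99, and 7 of 9 with scaling by library size only. Ms4a4b, a membrane protein of T cells, stood at 4868 ± 439 and 8530 ± 938 CPM, Ms4a6b at 985 ± 4.66 and 2279 ± 364 CPM and Ms4a4c at 770 ± 163 and 1603 ± 438 CPM. Members of both families share sequence, so the counts of single members are uncertain. With scaling by library size only the Ly6 median was 1.41.

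Interferon-inducible Ifi, Ifit and Ifitm genes lay higher in 26 of 27 cases, with a median of 0.72. The interferon response list also holds Ifi35, Ifit1, Gbp2 and Ly6a, so these families are not wholly separate results. Ifitm3 stood at 54.9 ± 31.9 CPM (SD, n = 2) in PBS and 220 ± 96.0 CPM (SD, n = 4) in IL-10/Fc, Ifitm2 at 25.2 ± 11.3 and 82.5 ± 8.83 CPM and Ifi47 at 215 ± 5.57 and 430 ± 92.2 CPM. Ifitm1 stood at 21.5 ± 5.63 CPM in PBS, at 2063 CPM in IL-10/Fc replicate 1 and between 175 and 381 CPM in the other 3. Guanylate-binding proteins lay higher in 11 of 11 cases, and in 10 of 11 with scaling by library size only, with Gbp2 at 63.5 ± 18.9 and 176 ± 63.5 CPM. Of 7 S100 genes 5 lay higher, and 4 with scaling by library size only, with S100a6 at 970.5 ± 3.56 and 2084 ± 540 CPM and S100a4 at 434 ± 136 and 805 ± 55.5 CPM. Of 76 Rpl and Rps genes 49 lay lower, with a median of -0.05, and 73 of 76 with scaling by library size only, with a median of -0.22.

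The 8 genes that follow were picked by hand from outside the lists, and none passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p from 0.141 to 0.272). Slamf7 stood at 84.1 ± 20.9 CPM (SD, n = 2) in PBS and 260 ± 60.4 CPM (SD, n = 4) in IL-10/Fc, Cd7 at 6.50 ± 0.320 and 89.8 ± 63.7 CPM, and the integrin chain gene Itgb7 at 23.2 ± 0.0475 and 81.2 ± 36.1 CPM. The common cytokine receptor chain Il2rg stood at 1052 ± 264 and 1896 ± 185 CPM, and the fatty acid elongase gene Elovl6 at 2.83 ± 0.172 and 19.2 ± 3.68 CPM. Lower in IL-10/Fc were Sh2d2a, an adaptor of T cell signalling, at 1567 ± 55.9 and 793 ± 141 CPM, Rgs16 at 72.4 ± 15.7 and 33.7 ± 1.47 CPM and Il18rap at 383 ± 95 and 222 ± 19.6 CPM. The authors' deposited table called each of these 8 genes in the direction given.

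Other groupings of the 6 libraries into 2 and 4 were tested as well. Of the 15 splits, 1, the real one, gave as many calls as the 1 gene of edgeR's test, and the highest other split gave 0. With DESeq2 the real split gave 738 calls and the highest other, IL-10/Fc replicates 1 and 2 against the rest, gave 146. With 15 splits a share under 0.05 cannot be reached.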
